A study of Arabidopsis thaliana with 8 samples.

How the data were processed

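Total RNA of Arabidopsis thaliana plants that overexpress the LAMMER kinase PK12 and of non-transformed plants had been hybridised to 2-colour EST arrays, 4 for plants of 10 days and 4 of another array type for plants of 21 days, per the labels. The deposited values are log10 ratios of the channels, as judged from the values: on 7 arrays, 10 raised to the value gave a ratio with 3 decimals, as tested on ratios under 3. On array 1 of 10 days 96.9% of values had at most 2 decimals, and values within 0.01 of 0, other than 0 itself, had more. All 375 values within 0.01 of 0 were log10 values of ratios with 3 decimals, against 6.13% for base 2, and the spread of the array (SD 0.277) was near that of the other 10-day arrays (0.222 to 0.252). The deposited log10 columns had medians within rounding of 0 on 7 arrays and of -0.000435 on array 1 of 10 days, so the authors had centred the arrays before deposit. The scanner, the dyes, the background correction, the dye normalization and the spot filters are not given in the sources used here, and neither is which channel is the numerator, so the direction of the ratio stays unknown. No label speaks of swapped dyes.

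Values were converted to log2 and each array was centred on its median. ESTs with a value on all 4 arrays of an age were tested, which left out 9 at 10 days and 17 at 21 days. The platform annotation paired 5216 ESTs of the 10-day type with a single gene, 73 with several and 6676 with none, and 3910, 54 and 4865 of the 21-day type. ESTs without a named gene were tested but are unnamed here. Entrez identifiers were brought to current symbols and locus codes through the gene table of assembly TAIR10.1, which matched 5209 and 3905 ESTs, for 3519 and 2917 genes. ESTs of a gene were averaged for tests on genes. No coordinates were used. Spot order and neighbouring spots below mean the order of the EST identifiers, which stood in for positions on the slide.

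Each age was fitted with limma (version 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, and statmod 1.5.0) as an intercept without covariates, with eBayes and Benjamini-Hochberg adjustment at 0.05. The ages were compared by limma on genes over all 8 arrays. Gene lists, 18 in number with 278 genes given by locus code, were drawn up before the data were examined. They were tested at 3 or more measured genes with camera at a preset correlation of 0.01, adjusted over the 10 tests of both ages, and again with an estimated correlation and with fry, whose adjusted p-values cover the same 10 tests. Named ESTs covered 26 of the list genes at 10 days and 24 at 21 days, the matches of the histone list included. Lists were compared between ages by an exact permutation test on the mean over the genes of each array. The labels state 4 arrays and 2 independent experiments per age without assigning them, so all arrays entered as separate samples, and the 3 possible pairings were tried as alternatives.

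Most genes named in the text were set by a rule fixed before the data were examined. The rule took the 10 largest means on either side among genes past the threshold with the same sign on all 4 arrays, and where fewer than 5 passed, the 5 largest of one sign on all arrays. It added every measured LAMMER kinase, the 2 highest and 2 lowest members of every list at each age, genes past the threshold at both ages (there were 0) and the 5 smallest adjusted p-values of the difference between ages. LHCB4.1, the H3.1 histone genes, PGY2, ICL and the members of gene families were named outside this rule, after the values had been seen. The main tests, the alternatives and the gene lists were also fixed before the data were examined. The removal of the local median over 36 spots on either side in spot order was added afterwards, as were the tests on ESTs shared by the array types, on separate ESTs of a gene and on matchings shifted along the array, and the pairings of arrays in the difference between ages. Other alternatives were no centring, scaling and quantile normalization between arrays, robust eBayes, a fold threshold, a rule without a test, genes in place of ESTs and leaving out each array in turn.

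The fits were tested on simulated data made from the real spread, with 100 ESTs or genes changed at each size. The simulated noise was independent between ESTs and between arrays. On the real arrays neighbouring spots were related and the 4 arrays of an age came from 2 experiments. The rates below may therefore be too favourable for the real data. At 10 days 47% of ESTs with a log2 change of 1 and 99% with a change of 2 were recovered, with 8 false among 154 calls. At 21 days 73% and 100% were recovered, with 12 false among 185 calls. For the difference between ages, 27% and 100% of genes were recovered, with 5 false among 132 calls.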

Results

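Transcript abundance was compared between Arabidopsis thaliana plants that overexpress PK12, a plant protein kinase of the LAMMER family whose members phosphorylate splicing factors, and non-transformed plants. Each of the 8 arrays was hybridised with total RNA from both kinds of plant, the non-transformed plants in channel 1 and the PK12 plants in channel 2. Plants grown for 10 days under long days were measured on 4 arrays printed with expressed sequence tags (ESTs), and plants grown for 21 days on 4 arrays of another type. Both types shared 3951 ESTs that were listed once on each and had a value on all arrays. The measurement is therefore a ratio between the channels at each spot, and no control array exists apart from the control channel. The labels give neither the dyes nor which channel is the numerator, so each gene is placed here on the positive or the negative side of the deposited ratio. The positive side would be the side of higher abundance in PK12 plants if channel 2 was divided by channel 1.

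At 10 days 11965 ESTs were present, of which 11956 had a value on all 4 arrays, and at 21 days 8829, of which 8812 did. After averaging the ESTs of a gene, 3517 named genes were tested at 10 days and 2913 at 21 days. No pair of arrays held identical values. The 4 arrays of an age include 2 independent biological experiments per the labels, which do not say which arrays share one, so the p-values below measure a spread between arrays that is partly technical. The files hold ratios without intensities, and the number of arrays limits the precision.

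The first question was which transcripts differed between PK12 plants and non-transformed plants at 10 days. Several transcripts for photosynthesis passed on the negative side and 2 of the 3 measured chaperone transcripts of the fixed list on the positive side. The 3 lists behind them did not pass camera when the correlation was estimated (light harvesting p = 0.127, Calvin cycle p = 0.134 and chaperones p = 0.0573 with an estimated correlation). Rubisco activase (RCA), which keeps the carbon-fixing enzyme of the Calvin cycle active, had the lowest mean of the genes past the threshold, a log2 ratio of -1.94 ± 0.65 (SD, n = 4 arrays), a 3.83-fold departure from equal channels. At the other end stood AT1G76960 at 3.56 ± 1.93 (11.8-fold) and AT2G38870, which encodes a proteinase inhibitor of the potato inhibitor I type, at 3.08 ± 0.53 (8.43-fold). The luminal binding protein BIP1, a chaperone of the endoplasmic reticulum, was at 1.27 ± 0.24 and the cytosolic chaperone Hsp70-2 at 1.23 ± 0.11. Both chaperones rested on 1 EST each.

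In limma, 2031 of the 11956 ESTs differed from equal channels at a Benjamini-Hochberg adjusted p under 0.05, 1026 on the positive and 1005 on the negative side. Their median absolute log2 ratio was 1.08, or 2.11-fold. All 4 arrays had the same sign for 42.2% of ESTs, where signs drawn at random would give 12.5%. By gene, 459 of 3517 passed, 283 positive and 176 negative. Array pairs correlated across ESTs at Pearson's r from 0.281 to 0.638, ESTs not being independent replicates. Leaving out any array lowered the count of ESTs past the threshold to between 1042 and 1210, and removing the local median of neighbouring spots, chosen after seeing the data, raised it to 3089.

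The 10 genes with the largest positive means were led by AT1G76960 (adjusted p = 0.0195 in limma) and AT2G38870 (adjusted p = 0.00205). AT5G42530 followed with a mean of 2.91 (1.56 to 4.45 over the 4 arrays) and PAP85, a vicilin-like seed storage protein, at 2.88 ± 2.20 (SD, n = 4). PAP85 owed its mean mostly to arrays 3 and 4, at 4.70 and 4.85, against 0.73 and 1.23 on arrays 1 and 2, and it no longer passed (limma adjusted p = 0.0485 with all 4 arrays) when any array was left out. PAP85 also did not pass with arrays 1 and 3 against 2 and 4 as a random block (limma adjusted p = 0.098). The same held with treat (0.0819) and with scaling between arrays (0.0504). AT1G76960 did not pass without array 1 (limma adjusted p = 0.0756), nor AT5G42530 without array 1 or 2 (0.0591 and 0.0543). AT1G76960 and AT5G42530 had the opposite profile, with 4.69 and 5.65 against 1.57 and 2.33 for the first, and 4.45 and 3.95 against 1.69 and 1.56 for the second. The others varied less between arrays. AT5G63940 lay at 2.73 ± 0.21, AT3G13650, a member of the dirigent family, at 2.72 ± 0.41, and AT1G26410, a berberine bridge enzyme-like oxidase, at 2.53 ± 0.76. AT3G26470 was at 2.44 ± 0.31, RAP, a chloroplast RNA-processing protein, at 2.42 ± 0.31, and AT4G09620 at 2.28 ± 0.15. Apart from PAP85, AT1G76960 and AT5G42530 (adjusted p = 0.018), these genes had limma adjusted p-values from 0.00205 to 0.00909. All 10 genes rested on 1 EST each.

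After RCA (limma adjusted p = 0.0103), the lowest means belonged to AT5G25820, a protein of the exostosin family, at -1.87 ± 0.41 and AT3G07180 at -1.77 ± 0.95 (SD, n = 4). AT2G30820 was at -1.75 ± 0.20, AT5G49440 at -1.69 (-2.72 to -0.80 over the 4 arrays) and AT4G29590 at -1.67 ± 0.67. AT3G43540 was at -1.60 ± 0.68, AT1G52870 at -1.59 ± 0.85, AT4G00910 at -1.54 ± 0.68 and AT3G56510 at -1.53 ± 0.16. Limma adjusted p-values of these 10 genes ran from 0.00453 for AT2G30820 to 0.0283 for AT5G49440. The same sign on all 4 arrays was a condition of their choice. Only RCA (5 ESTs) and AT5G49440 (2 ESTs) were measured by more than 1 EST. AT3G07180, AT5G49440, AT4G29590, AT1G52870 and AT4G00910 each lost the call when some single array was left out. AT5G49440 also lost it with arrays 1 and 3 against 2 and 4 as a random block (limma adjusted p = 0.0623) and with treat (0.0557).

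**Figure D1:**
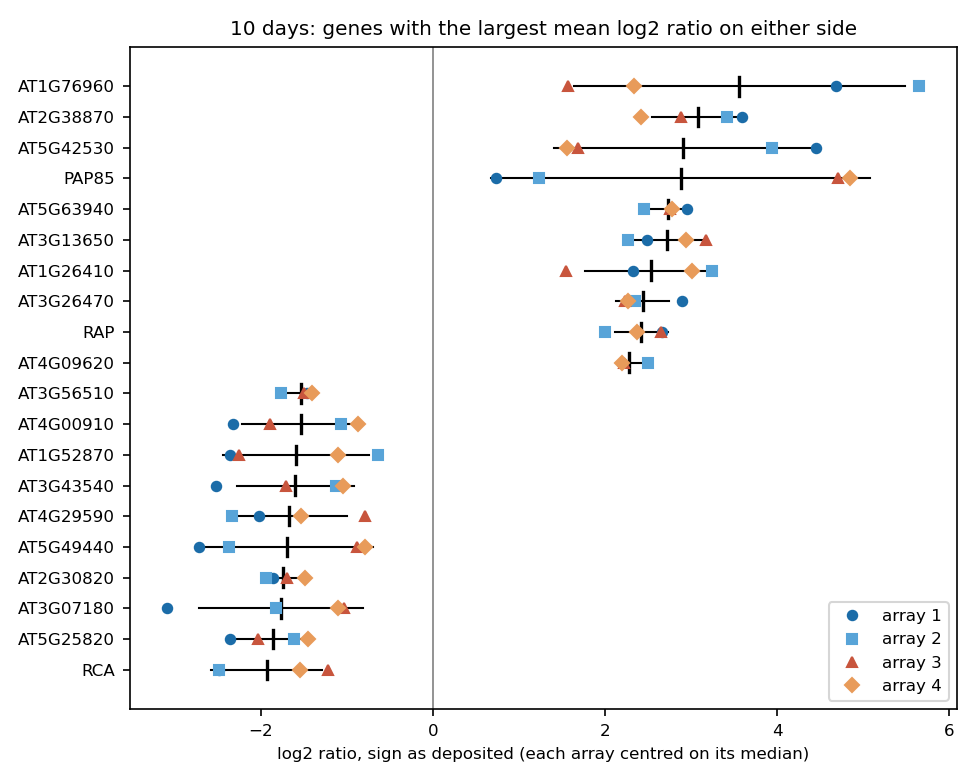
Log2 ratio at 10 days (horizontal axis, sign as deposited) of the 10 genes with the largest mean on either side of the ratio. Symbols are the 4 arrays, the vertical tick is their mean and the horizontal line 1 SD on either side. AT5G63940 at 2.73 ± 0.21 had similar values on all 4 arrays, while PAP85 at 2.88 ± 2.20 had its high values on arrays 3 and 4.

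Of the 39 genes in the fixed list for light harvesting and photosystems, 7 were measured by name at 10 days, and all had negative means. LHCB4.2, an antenna protein of photosystem II, was at -1.18 ± 0.09, PSAN, a subunit of photosystem I, at -1.13 ± 0.32, LHB1B2 at -1.07 ± 0.35 and LHCB4.1 at -0.80 ± 0.34 (SD, n = 4). These 4 passed the limma test over all genes, and the same number passed when adjusted over the list alone. PSAN did not pass without array 4 (limma adjusted p = 0.0528). PSAE-1 at -0.59 ± 0.61, PSBY at -0.23 ± 0.45 and PSBW at -0.09 ± 0.39 did not. The list passed camera with a preset correlation (adjusted p = 0.00178), and fry (adjusted p = 0.0247), but not camera when the correlation was estimated (p = 0.127 with an estimated correlation). ESTs of LHB1B2 did not all point the same way, their means running from -1.95 to 1.34 over 9 ESTs, and those of LHCB4.2 ran from -1.95 to 0.35 over 8.

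All 3 measured genes of the Calvin cycle list passed on the negative side. RCA was joined by phosphoribulokinase (PRK) at -1.43 ± 0.52 and sedoheptulose-bisphosphatase (SBPASE) at -0.70 ± 0.26 (SD, n = 4). The same 3 genes passed when adjusted over the list alone. The list passed camera (adjusted p = 0.00331) and fry (adjusted p = 0.0247), and the call was lost only in camera with the correlation estimated (p = 0.134 with an estimated correlation). SBPASE, with a limma adjusted p of 0.0407, no longer passed when any of the arrays was left out, and PRK did not without array 1 (adjusted p = 0.0568). SBPASE also did not pass with arrays 1 and 2 against 3 and 4 or 1 and 3 against 2 and 4 as 2 samples (limma adjusted p = 0.0626 and 0.133), with the second pairing as a random block (0.0759), with treat (0.147) or without the local median (0.0771).

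Of the 20 genes in the fixed list of heat shock proteins and chaperones, 3 were measured by name. Hsp70-2 (limma adjusted p = 0.00966) and BIP1 (adjusted p = 0.00985) passed on the positive side, each on 1 EST. AT3G09440, another cytosolic Hsp70, was at 0.53 ± 0.43 (SD, n = 4) over 4 ESTs and did not pass over all genes (limma adjusted p = 0.128). It did pass when adjusted over the list alone, which gave 3 positive genes. AT3G09440 also passed over all genes without the local median (adjusted p = 0.0495) and with arrays 1 and 4 against 2 and 3 as 2 samples (0.0193) or as a random block (0.00173). The estimated correlation within those pairs was -0.806, which narrows the error of the mean. The list passed camera (adjusted p = 0.00972) and fry (adjusted p = 0.00117), but not camera when the correlation was estimated (p = 0.0573 with an estimated correlation).

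The remaining lists gave no call at 10 days over all genes. The 3 genes of cold, dehydration and abscisic acid response split, with KIN2 at -0.90 ± 2.37, COR47 at -0.50 ± 0.57 and LTI30 at 0.11 ± 0.58 (SD, n = 4; camera adjusted p = 0.398). KIN2 was above 0 on arrays 1 and 2 and at -3.15 and -2.73 on arrays 3 and 4. The 3 histone genes found by the name rule also split, with HON4 at -0.40 ± 0.40, the linker histone HIS1-3 at 0.46 ± 0.44 and HIS4 at 0.50 ± 0.82 (camera adjusted p = 0.73). The histone H3.1 genes AT5G65360 at 0.71 ± 0.59 and AT5G10390 at 0.79 ± 0.37 (limma adjusted p = 0.1 and 0.0414) were measured but missed by that rule, so the list does not stand for all measured histones. The LAMMER kinase AME3, the relative of PK12 measured here, was at 0.25 ± 0.28 (limma adjusted p = 0.375). Of the splicing factors, the U2AF large subunits AT1G60900 and ATU2AF65A were at -1.36 ± 1.57 and -0.18 ± 0.10, neither passing with all 4 arrays as samples (limma adjusted p = 0.136 and 0.454). AT1G60900 passed with pairs of arrays as 2 samples under each of the 3 pairings (limma adjusted p = 0.00786, 0.0268 and 0.0137). As a random block it passed with arrays 1 and 4 against 2 and 3 (0.00172) and not with the other pairings. Its call therefore depends on whether pairs are averaged or blocked. The 4 arrays of AT1G60900 read -3.55, -0.73, -1.25 and 0.11. With 2 samples a gene's own spread weighs little in the eBayes error, so its calls under the 3 pairings carry little weight. EIN3, a transcription factor of ethylene signalling, was at -0.54 ± 0.18 (limma adjusted p = 0.0661) and passed when adjusted over the list alone, where it was the only gene (limma adjusted p = 0.0118). The cell wall expansin EXPA8 was at 0.46 ± 0.41, the phenylpropanoid gene HCT at 0.34 ± 0.21 and the root marker PYK10 at -0.25 ± 0.13, none of them past the threshold. With arrays 1 and 4 against 2 and 3 as a random block, EIN3, EXPA8, HCT, PYK10, KIN2, COR47 and the 3 histone genes found by the name rule passed as well. With the same pairs as 2 samples these genes passed too, except PYK10. The estimated correlation within these pairs was -0.806, so arrays of a pair were less alike than arrays of different pairs. Such a correlation narrows the error of the mean, so these calls carry little weight. Genes of the lists for salicylate, jasmonate, flowering time and the clock, senescence, seed storage and floral organ identity had no named EST at 10 days, or at 21 days, and were not analysed here, nor was the phenylpropanoid list at 21 days. Cytosolic ribosomal proteins were not analysed here as a list, because the gene names used do not carry the words that define it, although genes such as PGY2 were measured.

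The same comparison at 21 days gave no gene whose ratio could be told from equal channels. The photosynthesis genes that passed at 10 days had means nearer 0, with RCA at -0.11 ± 0.32, PRK at 0.05 ± 0.37, LHCB4.2 at -0.28 ± 0.26 and PSAN at -0.14 ± 0.24 (SD, n = 4). The chaperones BIP1 at 0.75 ± 1.43 and Hsp70-2 at 0.14 ± 0.45 varied more between arrays than at 10 days. COR47, a cold-responsive dehydrin, was at -0.61 ± 0.16 and SBPASE at -0.46 ± 0.19, and neither passed over all genes (limma adjusted p = 0.486 and 0.536). ESTs of COR47 did not all point the same way. Their means ran from -1.12 to 0.19 over 3 ESTs at 21 days and from -1.22 to 0.14 over 4 at 10 days.

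In limma, 0 of 8812 ESTs and 0 of 2913 genes passed, and the smallest adjusted p over ESTs was 0.297. Robust eBayes, treat and quantile normalization also gave 0 ESTs. At an unadjusted p under 0.05 there were 890 ESTs (10.1%) and 266 genes. The 890 ESTs became 743 when the local median of neighbouring spots was removed, a setting chosen after seeing the data. The sign was shared by all 4 arrays for 17.5% of ESTs, and 29 ESTs were at least 1.5-fold from equal channels in the same direction on every array. Array pairs correlated at Pearson's r from -0.067 to 0.385, array 1 with the others at -0.067, 0.082 and -0.019. When the means of arrays 1 and 2 and of arrays 3 and 4 were taken as 2 samples, 239 ESTs passed. With those pairs as a random block 71 passed. The estimated correlation within those pairs was -0.362, so arrays of a pair were less alike than arrays of different pairs. This narrows the error of the mean, so these counts carry little weight.

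The genes with the largest means among those of one sign on all 4 arrays are given although none passed with all 4 arrays as samples (limma adjusted p from 0.443 to 0.486). All 10 passed when arrays 1 and 2 against 3 and 4 were taken as 2 samples (0.0086 to 0.0207). None passed with those pairs as a random block or under another pairing. Arrays of those pairs were less alike than arrays of different pairs, so the 10 calls carry little weight. On the positive side AT5G01090 was at 1.25 ± 0.74, AT1G08340 at 1.25 ± 0.93, AT1G27850 at 1.09 ± 0.53, AT2G43535 at 1.07 ± 0.82 and AT2G35450 at 1.03 ± 0.83 (SD, n = 4). On the negative side AT5G01430 was at -1.19 ± 0.82, the ubiquitin-conjugating enzyme UBC34 at -1.17 ± 0.81, AT4G27350 at -1.11 ± 0.45, AT1G48650 at -1.07 ± 0.99 and AT3G60080 at -1.06 ± 0.69.

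None of the 5 lists tested at 21 days passed camera. The cold, dehydration and abscisic acid list came nearest (camera adjusted p = 0.0789), with KIN2 at -0.41 ± 0.61 and LTI30 at -0.01 ± 0.48 beside COR47. Of its 3 genes 1 passed when adjusted over the list alone, COR47, whose ESTs differed in sign. The 6 light harvesting genes had a median log2 ratio of -0.24 (camera adjusted p = 0.148), among them LHB1B2 at -0.41 ± 0.14, PSAE-1 at -0.31 ± 0.12, LHCB4.1 at -0.20 ± 0.18 and PSBW at 0.66 ± 1.21 (SD, n = 4). Adjusted p-values in camera were 0.3 for the Calvin cycle, 0.264 for heat shock proteins and chaperones, where AT3G09440 was at 0.24 ± 0.79, and 0.306 for the histones, where HON4 was at -0.55 ± 0.31, HIS1-3 at 0.06 ± 0.21 and HIS4 at -0.04 ± 0.17. Of the lists with fewer than 3 measured genes, AME3 was at -0.01 ± 0.20, AT1G60900 at -0.38 ± 0.44, ATU2AF65A at -0.08 ± 0.19, EIN3 at -0.00 ± 0.38, EXPA8 at 0.23 ± 0.32 and PYK10 at 0.44 ± 0.33. With fry, which asks whether a list's genes move one way on balance, the cold and light harvesting lists passed at 21 days (adjusted p = 0.00117 and 0.0115), while in camera they did not (cold p = 0.118 and light harvesting p = 0.165 with an estimated correlation).

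**Figure D2:**
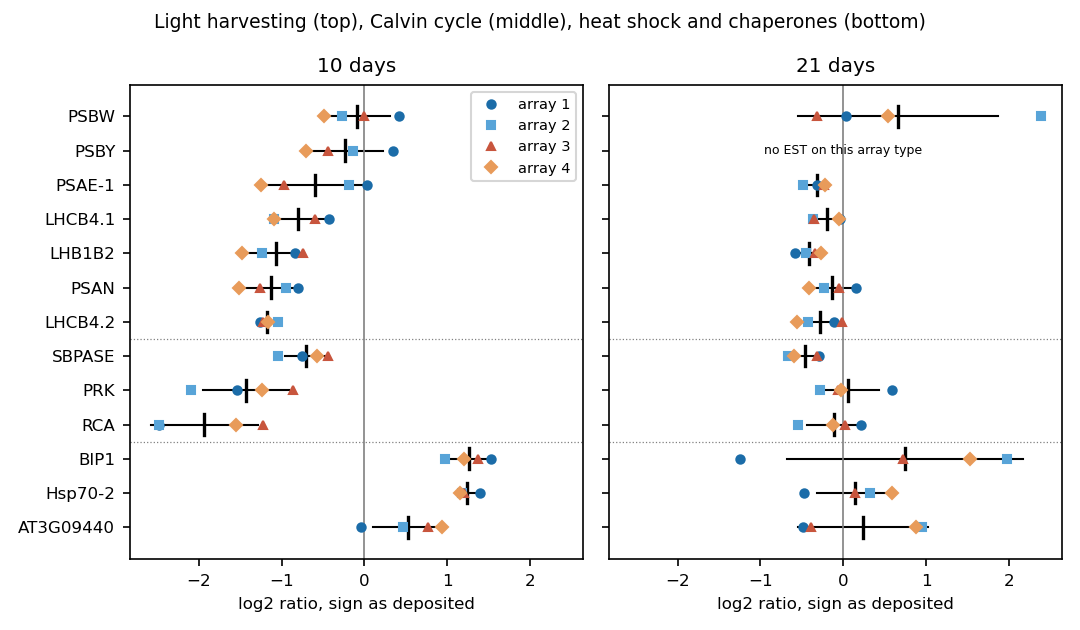
Log2 ratio (horizontal axes, sign as deposited) of the measured genes of the lists for light harvesting, the Calvin cycle and heat shock proteins and chaperones at 10 days (left) and 21 days (right), with the 4 arrays of each age as symbols, their mean as a tick and 1 SD on either side as a line. RCA had a mean of -1.94 at 10 days and -0.11 at 21 days.

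A further comparison asked whether the ratios differed between the ages. Several of the largest departures at 10 days were not seen at 21 days. Those genes were chosen for their size at 10 days, which by itself favours a fall. AT5G63940 went from 2.73 ± 0.21 at 10 days to -0.06 ± 0.44 at 21 days (SD, n = 4 at each age) and AT3G13650 from 2.72 ± 0.41 to -0.25 ± 0.50, the smallest limma adjusted p-values of the difference (0.000933 for both). AT5G42530 (0.96 at 21 days, with a high spread between arrays) and PAP85 (-0.18) did not pass for the difference (limma adjusted p = 0.221 and 0.0575). RCA rose from -1.94 to -0.11, a difference of 1.82 (SE 0.34, limma adjusted p = 0.0152), and PRK from -1.43 to 0.05, a difference of 1.49 (SE 0.32, adjusted p = 0.0261). The other genes of the photosynthesis lists past the threshold at 10 days did not pass for the difference, with limma adjusted p of 0.0577 for PSAN, 0.0637 for LHCB4.2, 0.16 for LHB1B2, 0.201 for LHCB4.1 and 0.619 for SBPASE.

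Over the 2913 genes measured on both array types, the ratio differed for 101 in limma, 38 of them higher and 63 lower at 21 days, and 88 of the 101 were past the threshold at 10 days. With the 21-day sign turned 178 differed, 71 higher and 107 lower, of which 46 were among the 101 and 150 past the threshold at 10 days. AT1G03106, AT3G26470 and AT2G39710 completed the 5 smallest adjusted p-values of the difference (0.00213, 0.00213 and 0.00332), with 10-day means of 1.91 ± 0.10, 2.44 ± 0.31 and 1.49 ± 0.39 and 21-day means of 0.01 ± 0.16, -0.04 ± 0.51 and -0.52 ± 0.14 (SD, n = 4). The 2 ESTs of AT1G03106 had 10-day means of -0.33 and 4.14, so its value is uncertain. The age of the plants and the array type changed together and cannot be told apart. The count fell to 40 when array 4 of 21 days was left out. With pairs of arrays averaged to 2 samples per age it was anywhere from 0 to 394 by pairing, the 394 with arrays 1 and 4 against 2 and 3 at 10 days. At 10 days separate ESTs of a gene shared the contrast of arrays 1 and 2 with 3 and 4 (r = 0.372) more than the other contrasts of pairs (0.064 and 0.011). With that pairing at 10 days the count was 86, 0 or 14 by the 21-day pairing. The labels do not name the pairs, so the count of 101 is uncertain and may fall to 0.

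Of the lists, light harvesting had a mean log2 ratio of -0.81 ± 0.28 over 6 genes at 10 days and -0.11 ± 0.13 at 21 days, and the Calvin cycle of -1.36 ± 0.46 and -0.17 ± 0.28 over 3 genes (SD, n = 4 arrays). Both differed in an exact permutation test of the 8 arrays (p = 0.0286, the smallest that 70 splits can give, adjusted p = 0.0477 over 5 lists), which takes the arrays of an age as independent. The histones differed by as small a p, from 0.19 ± 0.17 to -0.18 ± 0.10, but with the 21-day sign turned their difference was -0.01 (exact permutation p = 0.914), so it rests on an unknown direction. Light harvesting and the Calvin cycle differed under either sign. Heat shock proteins and chaperones, at 1.01 ± 0.12 and 0.38 ± 0.85, and the cold list, at -0.43 ± 1.12 and -0.35 ± 0.05, did not (exact permutation p = 0.286 and 0.971). With the 21-day sign turned, heat shock proteins and chaperones differed (exact permutation p = 0.0286, adjusted p = 0.0477).

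Mean ratios of the ages correlated across the 2913 genes at Pearson's r = 0.058 and Spearman's rho = 0.062, genes not being independent replicates, and single arrays of the ages at r from -0.106 to 0.089 over 16 pairs. Of the 357 genes past the threshold at 10 days and measured at 21 days, 202 (56.6%) lay on the same side at 21 days, or 155 (43.4%) with the 21-day sign turned. Their median absolute log2 ratio was 0.99 at 10 days and 0.18 at 21 days. They were chosen by their 10-day values, which by itself favours a smaller ratio at 21 days. Over all 2913 genes the SD of the mean ratios was 0.55 at 10 days and 0.31 at 21 days. With 0 genes past the threshold at 21 days the overlap of calls had no test. The direction of either age's ratio is open, and with the 21-day sign turned r was -0.058.

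**Figure D3:**
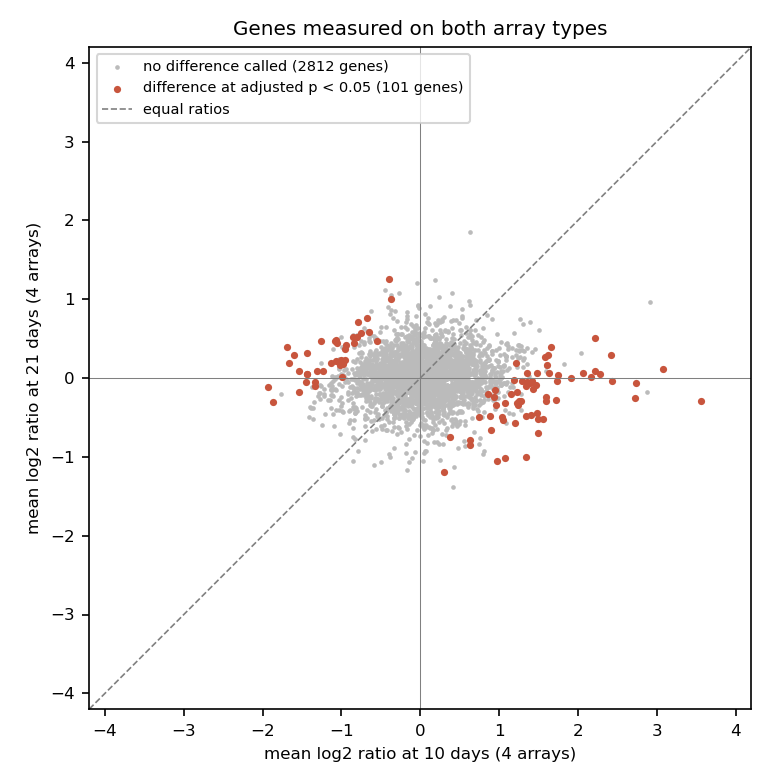
Mean log2 ratio of each of the 2913 genes at 10 days (horizontal axis) against 21 days (vertical axis), 4 arrays each, with the 101 genes that differed between ages at an adjusted p under 0.05 in red and the dashed line at equal ratios. The red genes lie mostly along the horizontal axis, far from 0 at 10 days and near 0 at 21 days.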

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

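The tests of spot position, of ESTs shared by the array types and of separate ESTs of a gene were chosen after the results they measure had been seen, while the sign patterns, the splits of arrays, the neighbouring spots and the reserve list were set before.

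A gap between an array and the other 3 beyond Dixon's limit was found in 3 of 74 named gene and age pairs, where chance gives about 1 in 20, or 3.7. AT4G09620 read 2.50 on array 2 of 10 days (mean of the others 2.20), LTI30 read -0.75 on array 3 of 10 days (mean of the others 0.40) and AT1G27850 read 1.86 on array 4 of 21 days (mean of the others 0.83).

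Between the ages, 18 of 50 named genes measured at both had different ratios in limma with the deposited signs. Many of the named genes were chosen for large ratios at an age or for the difference itself. Their share is therefore not comparable with the 101 of 2913 over all genes. With the 21-day sign turned, 13 of the 18 still passed, on the same side, while AT2G39710, AT5G01090, AT5G49440, AT3G43540 and AT5G01430 did not. AT5G01090 (-0.86) and AT5G01430 (0.90) also changed side. Lower at 21 than at 10 days were AT5G63940 by -2.79, AT3G13650 by -2.97, AT1G03106 by -1.90, AT3G26470 by -2.47, AT2G39710 by -2.01, AT2G38870 by -2.95, RAP by -2.13, AT1G76960 by -3.85 and AT5G01430 by -1.49 on the log2 scale. Higher at 21 days were AT3G56510 by 1.63, AT5G25820 by 1.56, RCA by 1.82, AT4G29590 by 1.86, PRK by 1.49, AT5G01090 by 1.64, AT5G49440 by 2.09, AT3G43540 by 1.89 and AT4G00910 by 1.37. Adjusted p-values ran from 0.000933 for AT5G63940 to 0.0491 for AT4G00910. In all, 101 genes differed, and of the lists light harvesting differed by 0.70, the Calvin cycle by 1.18 and the histones by -0.36, each on the log2 scale (the histones by -0.01 with the 21-day sign turned). Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many genes, and the highest of the other splits gave 0. These splits break up the 2 experiments of an age, and 4 experiments kept whole allow 3 divisions, too few for a share under 0.05, so chance is left open. Array type remains an open explanation beside age.

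The 2031 ESTs past the threshold at 10 days could come from the order of the spots or from a bias of single ESTs towards a dye. Ratios of neighbouring spots were related, most of all in the contrast of arrays 1 and 3 with arrays 2 and 4 (rank correlation of neighbours 0.603), but removing the local median raised the count to 3089. A bias carried by the ESTs themselves could recur on the other array type. The 3951 ESTs listed once on each type, with a value on all arrays, had mean ratios with r = 0.063 between the ages. The 21-day arrays shared little among themselves (mean r of array pairs 0.108), and the dyes of every array are unknown. This r therefore cannot decide on such a bias, which stays open. Of the 8 sign patterns of the 4 arrays only 1, the real one, gave as many ESTs, the highest other count being 0, and 8 patterns are too few for a share under 0.05. A difference between the plants stays open as the biological explanation, as do differences between the cultures from which the RNA came.

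The 21-day arrays shared little, with a mean correlation over array pairs of 0.108 against 0.504 at 10 days. Removing the local median left it at 0.079, against a trend along the spot order as the cause of the low correlation. What the 21-day arrays did share may still be such a trend. In their mean, neighbouring spots had a rank correlation of 0.305, and separate ESTs of a gene an r of 0.038. At 10 days these were 0.182 and 0.367. An array hybridised the other way round could hide a shared signal, but no other sign pattern of the 4 arrays gave more than 8 ESTs past the threshold. Real differences that varied between arrays would be seen by separate ESTs of a gene on the same array, and these correlated at a median r of 0.052 within single 21-day arrays, against 0.292 at 10 days. The median SD of an EST between arrays was 0.454 at 21 days and 0.430 at 10 days. The SD of the mean ratios over ESTs was 0.350 at 21 days and 0.657 at 10 days. The spread between arrays was thus alike at both ages, and the mean ratios were smaller at 21 days. Noise that is large beside these smaller ratios may be a candidate explanation. Whether the smaller ratios come from older plants or from the array type was not tested.

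At 10 days a set of transcripts parted arrays 1 and 2 from arrays 3 and 4, with 112 ESTs at a split (mean of arrays 3 and 4 minus mean of arrays 1 and 2) of at least 2 on the log2 scale to either side. A local blemish would reach the neighbours of these ESTs if identifiers follow positions on the slide. The median absolute split of the neighbours was 0.398, close to the 0.361 of all ESTs. Slide positions were not used, so a blemish is not excluded. The split correlated between separate ESTs of a gene at r = 0.372 over 1025 EST pairs, where the contrast of arrays 1 and 3 with 2 and 4 gave 0.064, which is consistent with a difference in the RNA. Seed storage (PAP85) and reserve use (isocitrate lyase, ICL, noticed afterwards, with a positive split in each of 7 ESTs, median 1.79) lay on one side and KIN2 on the other, so plants of differing stage are a candidate explanation. It had no test, since 0 of 21 further reserve genes were measured, and the labels do not say which arrays share an experiment.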

How the results depend on the processing

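The removal of the local median of neighbouring spots and the pairings of arrays in the difference between ages were chosen after seeing the data, and the other settings were set before. The 10-day count of 2031 ESTs stayed within 1.5 times under 8 of 15 settings. It was 1109 with 1.5-fold on every array and no test, 459 for genes, 996 with treat, 1171 with arrays 1 and 3 against 2 and 4 as a random block, 6499 and 7538 with arrays 1 and 4 against 2 and 3 as 2 samples and as a random block, and 3089 without the local median. It was 1042, 1139, 1210 and 1188 without array 1, 2, 3 and 4, where fewer arrays were tested. The fold rule, the gene count and treat test fewer features or a stricter hypothesis by construction. For the pairings the cause was not tested. As a random block, arrays 1 and 4 against 2 and 3 had an estimated correlation of -0.806, which narrows the error of the mean. At 21 days the count of 0 became 29 under the fold rule and 0 to 3 with an array left out (3 without array 1). It was 239 and 71 with arrays 1 and 2 against 3 and 4 as 2 samples and as a random block. The estimated correlation within those 21-day pairs was -0.362, which narrows the error of the mean. The count of 101 genes differing between ages became 61 with quantile normalization, 178 with the 21-day sign turned, 170 without the local median and 40 to 92 with an array left out, with 46 without array 1 of 10 days and 51, 61 and 40 without arrays 2, 3 and 4 of 21 days. With pairs of arrays averaged to 2 samples per age it was 86, 0 and 14 for arrays 1 and 2 against 3 and 4 at 10 days, 54, 7 and 16 for 1 and 3 against 2 and 4, and 394, 67 and 392 for 1 and 4 against 2 and 3, with the same pairings in that order at 21 days, and the cause was not tested. The correlation between ages reversed to -0.058 with the sign turned, by construction, and was 0.033 to 0.080 with an array left out. The 3 lists past the threshold at 10 days became 0 with an estimated correlation, and stayed 3 without any array. At 21 days the count of lists went from 0 to 2 with fry and to 0 to 1 with an array left out (heat shock proteins and chaperones without array 1). The 20 genes with the largest means at 10 days were chosen for the same sign on all 4 arrays. Leaving out, averaging or blocking arrays therefore could not turn their sign. Robust eBayes and treat leave the mean as it is, scaling keeps the sign on every array, and leaving out the centring barely moved the values. Quantile normalization and removal of the local median could have turned the sign of these genes, and it was kept with both. With an array left out, 13 to 19 of them passed. No filter on dim spots was run, because the files hold no intensities. No paired analysis was possible because the ages share no plants or array type and each ratio already pairs both kinds of plant. Signal over background is unknown, which limits what can be said of weak spots.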

Other observations

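The matchings shifted along the array were chosen after the correlation between ages had been seen, and the test of families was set before its result was.

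Gene families read from symbols, with at least 5 measured genes, were tested beyond the fixed lists. None passed camera at 10 days (0 of 13 families, smallest adjusted p = 0.103) or at 21 days (0 of 8, smallest adjusted p = 0.843). At 10 days cytochrome P450 genes of the CYP71B group lay on the positive side, with CYP71B19 at 1.15 ± 0.52, CYP71B6 at 0.96 ± 0.35 and CYP71B20 at 0.83 ± 0.39 past the limma threshold over all genes and CYP71B28 at 0.56 ± 0.04 not (SD, n = 4). The fifth gene of that symbol family, CYP71, is a cyclophilin and was at -0.11 ± 0.27. All 5 alpha-tubulin genes had negative means, from -0.92 ± 0.74 for TUA5 to -0.15 ± 0.20 for TUA1, and none passed. Of the 5 TRM genes, TRM28 at 0.93 ± 0.21 and TRM21 at 0.65 ± 0.21 passed.

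The correlation between ages is small, and both array types carry spot-order trends, so the trends alone could produce it. Matching each 10-day EST to a spot shifted along the 21-day array gave an r as large as the 0.063 of the true match in 0.25% of 8000 shifts, or 0.662% counting either sign, with shifted values from -0.093 to 0.082. Neighbouring shifts are not independent. A weak relation between the ages that follows the ESTs may remain, and its sign cannot be told while the direction of the ratios is open.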
